A study of Mus musculus with 8 samples.

How the data were processed

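The series holds 8 RNA-seq libraries of mouse bone marrow LSK cells, 4 from vehicle and 4 from TAK-243 treatment. Group and replicate were taken from the sample titles, and the inhibitor is spelled differently in the submitters' design text. RNA was processed with a SMARTer stranded total RNA kit per the labels' protocols, which also name a SMARTer mRNA kit for the libraries. Reads were aligned with STAR to mm10 per the submitters' processing notes, and the table's name points to Rsubread for counting. The versions, annotation, strand setting, treatment of multiply mapped reads and any read trimming are not given in the sources used here. Because the use of strand in counting is unknown, reads of a gene and an overlapping antisense gene cannot be told apart. Genes with near-identical copies (histone, ribosomal protein and interferon-inducible GTPase genes) are uncertain for the same table.

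The deposited value is a count of reads per gene: the values are whole numbers with a different total in each library, so they were taken as not normalised. The table has 55367 gene symbols in 8 libraries, of which 9304 have a count of 0 in every library, and no blank or repeated name. No column was left unmatched to a sample. The deposited start and end positions matched a single exon of the gene for 99.5% of the 53292 symbols found in GENCODE M21 (mm10; 96.3% of all symbols), and the deposited length matched the merged exons for 98.9%. Gene coordinates given here are therefore those of the GENCODE M21 gene models.

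Total counts were 40887723, 44567478, 44769010 and 36396734 in vehicle replicates 1 to 4 and 37141778, 26531070, 13675642 and 38352933 in TAK-243 replicates 1 to 4. Counting error is therefore largest in TAK-243 replicate 3. No pair of libraries agreed within sampling noise: the chi-square per gene between libraries was at least 28.8, over genes with at least 100 counts in the pair. Sex-linked genes had the same pattern in all 8 libraries.

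Genes were kept with edgeR's filterByExpr defaults, which left 21930 genes holding 99.8% of counts, and libraries were scaled with TMM factors. The group difference was tested with edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM for correlations and per-library list medians add a prior count of 2. The common dispersion was 0.127.

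Before the data were examined, 36 gene lists, the rule for named genes, the tests and most alternatives were fixed. The lists cover ubiquitin and proteasome genes, stress responses, cell cycle, ribosome and energy metabolism, blood cell states, other cell types, and signs of RNA quality, plus 1 list of sex-linked genes used only as a sample check. The other 35 were tested with camera in limma 3.58.1, with an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. A list's members were also counted with p adjusted over the list alone. With the preset correlation 13 lists were called, 3 higher and 10 lower in TAK-243. With an estimated correlation 0 were called (smallest adjusted p = 0.468, limma), fry called 0 in its directional form (smallest adjusted p = 0.0728, limma) and 8 in its mixed form. The preset value can be too small where members vary together between libraries. The per-library medians of all 35 lists were also compared by a two-sided exact permutation test, chosen after the list results were seen. Of the 13 called lists, 4 had groups that did not overlap (exact permutation p = 0.0286). For the other 9 the groups overlapped, with an exact permutation p of 0.0857 to 0.571. These p-values were not adjusted over the 35 lists. Each gene was centred on the mean of the real vehicle libraries and not again for each split, so the p-values are approximate.

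The rule for named genes took Uba1, up to 10 genes in each direction with the largest change among those called, at a mean of at least 5 CPM, with groups that do not overlap and without unnamed gene models. Where fewer than 10 were called, it took them all and then filled up to 5 per direction by unadjusted p, said not to pass. It also took up to 4 members of each described list with the smallest p, and the most abundant member of each list of another cell type. The values of 1 gene that this rule names are not reported here. Single values per library were compared with a two-sided exact permutation test over all 70 splits of the 8 libraries.

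The alternatives fixed then were RLE, upper-quartile and total-count scaling, no filter and a stricter filter on low counts (at least 1 CPM in at least 4 libraries and a mean count of at least 20), DESeq2 1.42.0, limma-voom with sample quality weights, a replicate block, the number range of the library name as a covariate, removal of abundant RNA classes, a test against a fold of 1.5, a threshold of 0.10 and leaving out each library in turn. Chosen after seeing the data were a fit without TAK-243 replicates 2 and 3, subtraction of a background in proportion to gene length, an offset for GC content and length (natural splines with 5 degrees of freedom; 97.2% of tested genes had a GC value), and that offset together with the number range. To set the calls against chance, the same fits were run on all 35 ways to split the 8 libraries into 4 and 4.

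The methods were tested on simulated data drawn from the real means, library sizes and dispersions of the 21930 genes, with 200 genes above 5 CPM changed between TAK-243 and vehicle. edgeR recovered 7 of 68 genes changed by 1.5-fold, 24 of 66 changed by 2-fold and 64 of 66 changed by 4-fold, with 7 false calls. DESeq2 recovered 17, 46 and 65 of the same genes with 51 false calls, and limma-voom with quality weights 6, 25 and 62 with 4 false calls. A G2/M list lowered by 1.6-fold was called, with 18 of its 26 members past the threshold over the list alone, and 0 of the 34 other lists were called. The real split of the simulated libraries called 107 genes and the other splits at most 2. Genes were drawn independently of each other and without the library structure of the real data, so these results do not carry over to correlated genes. In the real data, other splits called up to 51 genes by edgeR and up to 17 lists.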

Results

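RNA-seq counts were available for 8 libraries of mouse bone marrow LSK cells, the lineage-negative, Sca-1-positive, Kit-positive compartment that holds haematopoietic stem cells and multipotent progenitors. 4 libraries came from vehicle treatment and 4 from treatment with TAK-243, a small-molecule inhibitor of UBA1, the main E1 enzyme that activates ubiquitin. The series title concerns lowered UBA1 expression in myelodysplastic syndrome, so the comparison asks how blood stem and progenitor cells respond when this enzyme is inhibited. Dose, duration and whether animals or cultured cells were treated are not given in the sources used here. Nor do the labels say that the 4 libraries of a group came from separate animals, so p-values measure the spread between these libraries. The total count ran from 36396734 to 44769010 in the vehicle libraries and from 13675642 to 38352933 in the TAK-243 libraries, and 21930 genes were tested.

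TAK-243 replicate 3 stood apart from the other libraries in several measures. Its median Pearson correlation with the others, over log2 CPM (counts scaled by library size) across genes, was 0.900, while the other 7 libraries had medians between 0.95 and 0.973. Mitochondrial genes took 1.66% of its counts and 5.12% of those of TAK-243 replicate 2, against 8.32% to 9.33% in vehicle. Over all libraries, the mitochondrial share was 5.81% ± 3.19 (SD, n = 4) in TAK-243 and 8.67% ± 0.457 (SD, n = 4) in vehicle, a difference that did not pass a two-sided exact permutation test (p = 0.114). Ribosomal protein genes took 3.97% ± 0.454 and 4.63% ± 0.246 (SD, n = 4 each; exact permutation p = 0.0571). The smallest p that 4 against 4 libraries allow is 0.0286. None of the 8 library measures compared in this way passed, with a smallest Benjamini-Hochberg adjusted p of 0.229 (exact permutation).

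**Figure D1:**
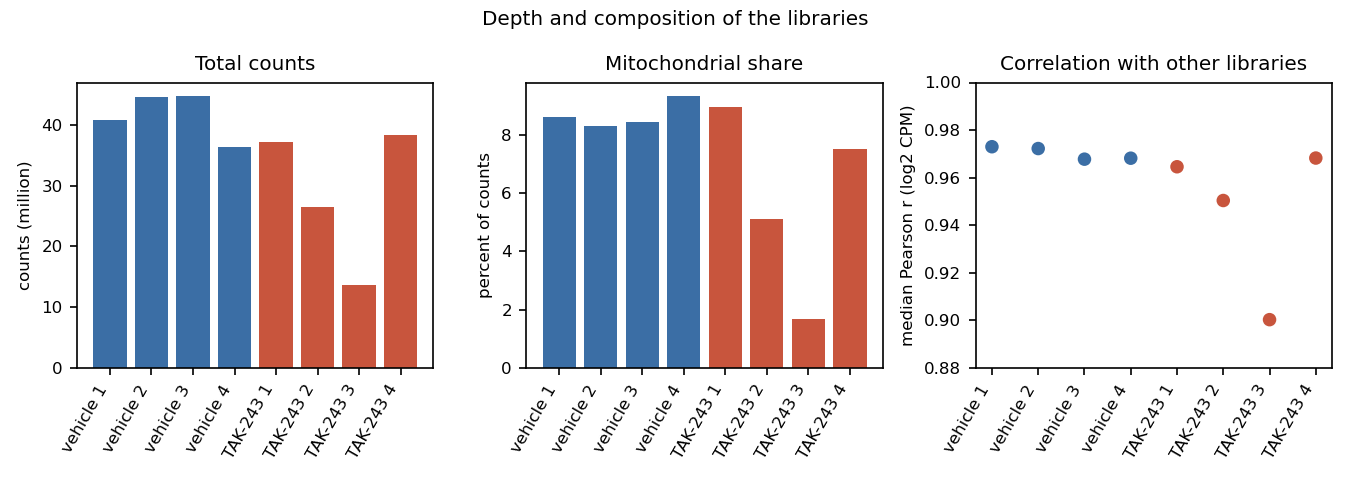
Total counts, the mitochondrial share of counts in percent, and the median Pearson correlation with the other libraries (axis from 0.88 to 1), for the 4 vehicle libraries (blue) and the 4 TAK-243 libraries (red). TAK-243 replicate 3 has the smallest total, 13675642, the smallest mitochondrial share, 1.66%, and the lowest correlation, 0.900.

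The first question was which transcripts differ between TAK-243 and vehicle, and whether the target's own mRNA does. Uba1 mRNA stood at 250.3 ± 44.2 CPM in TAK-243 and 277 ± 12.3 CPM in vehicle (SD, n = 4 each). Its log2 fold change was -0.15 (SE 0.13; edgeR adjusted p = 0.735), lower than the vehicle mean in 3 of the 4 TAK-243 libraries. Transcripts with the smallest p among those lower in TAK-243 included Psrc1, a microtubule-binding protein of the spindle, and Nusap1, a spindle protein; transcripts higher in TAK-243 included Itga2b, which encodes the integrin CD41 of megakaryocytes and early progenitors. No gene was called by edgeR's quasi-likelihood test at an adjusted p under 0.05, where the smallest adjusted p was 0.0511. At an unadjusted p under 0.05, 2430 genes stood out, 1283 higher and 1147 lower in TAK-243, where 1096.5 are expected by chance. DESeq2 called 462 genes (196 higher, 266 lower) and limma-voom with sample quality weights 109 (26 higher, 83 lower), of which 87 were shared. Leaving out 1 library changed the count of 0 for 3 of them: edgeR called 2 genes without TAK-243 replicate 2, 4 without TAK-243 replicate 4 and 49 without TAK-243 replicate 3 (11 higher, 38 lower). Without TAK-243 replicates 2 and 3, an alternative chosen after seeing the data, it called 140 (18 higher, 122 lower). In 1597 genes, or 7.28%, the groups did not overlap, where chance gives 2.86%.

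Since none passed, the 5 genes per direction with the smallest p among those at a mean of at least 5 CPM whose groups did not overlap are given with their values. Psrc1 (ENSMUSG00000068744.12, chromosome 3, 108383839 to 108388231, mm10) had 8.51 ± 1.00 CPM in TAK-243 and 23.9 ± 4.23 in vehicle (SD, n = 4 each), a log2 fold change of -1.49 (SE 0.18; edgeR adjusted p = 0.0511). Serpinf1, which encodes the secreted factor PEDF, stood at 19.0 ± 3.16 and 40.2 ± 1.44 CPM (log2 fold change -1.08; edgeR adjusted p = 0.0511). Nusap1 (chromosome 2, 119618298 to 119651244) had 45.5 ± 8.41 and 96.0 ± 7.92 CPM. Trib2, a pseudokinase, had 4.28 ± 1.00 and 12.3 ± 1.21 CPM, and Gas6, a ligand of the TAM receptor tyrosine kinases, 2.63 ± 0.871 and 10.2 ± 2.12 CPM, a log2 fold change of -1.95 (SE 0.28). Among those higher, Itga2b (chromosome 11, 102453297 to 102470122) stood at 189 ± 33.3 CPM in TAK-243 and 88.7 ± 16.1 in vehicle (log2 fold change 1.09; SE 0.17; edgeR adjusted p = 0.0741). St8sia6, a sialyltransferase, had a log2 fold change of 1.56, Krt80 of 1.26, the small GTPase Rab44 of 1.10 and the syntaxin Stx3 of 0.78. Over 22 alternatives each of these genes passed in some, from 3 for Rab44 to 9 for Psrc1 and 10 for Serpinf1. For each of these 10 genes all 4 TAK-243 libraries lay on the stated side of the vehicle mean. The rule of groups that do not overlap fixes this in advance. The coordinates are those of GENCODE M21 gene models, and the counts are over exons.

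**Figure D2:**
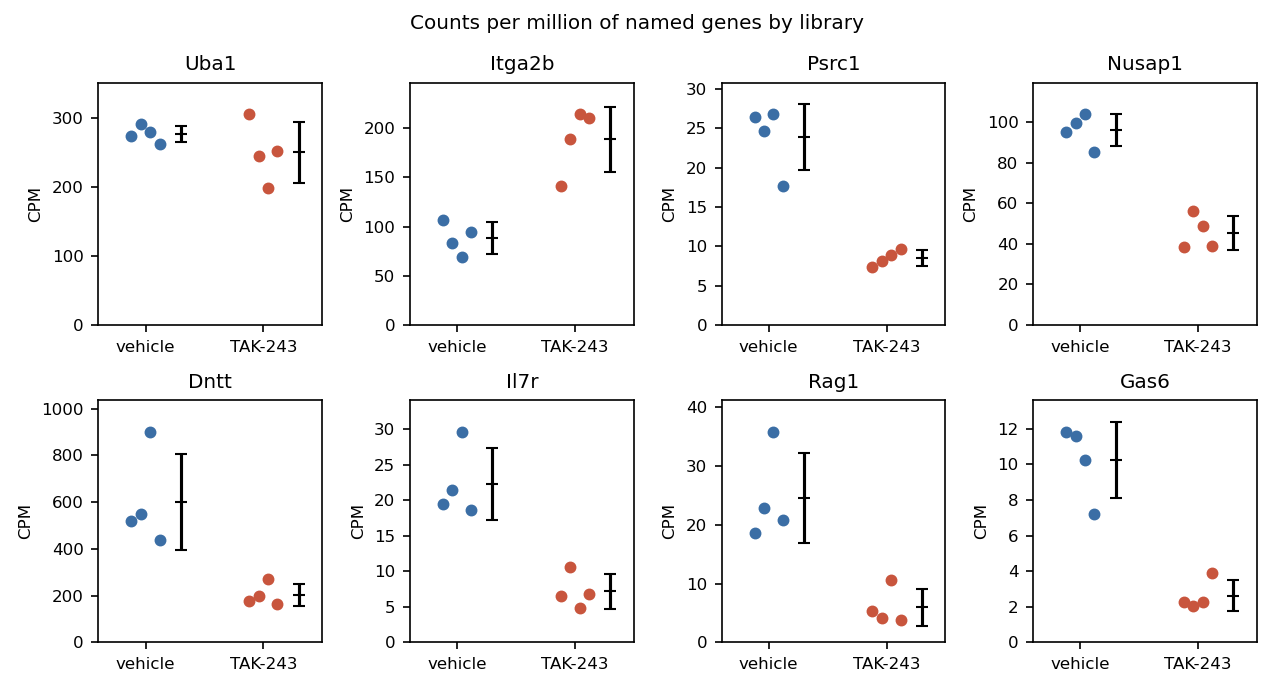
CPM (linear axes from 0) of 8 genes in each vehicle library (blue points) and TAK-243 library (red points), with the mean ± SD of the 4 libraries in black. Uba1 overlaps between groups, while the other genes shown do not, and none passed an adjusted p of 0.05 in the edgeR fit of all 8 libraries with no setting altered.

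Genes of the G2 and M phases of the cell cycle were lower under TAK-243. All 26 measured members of this list had a negative log2 fold change, with a median of -0.68, and 20 of them fell when p was adjusted over the list alone, against 0 when adjusted over all genes tested (edgeR). Nusap1 (-1.08), Ube2c, the E2 enzyme of the anaphase-promoting complex (-1.73), Cdc20, that complex's coactivator (-0.91), and the cyclin gene Ccna2 (-0.80) had the smallest p. Ube2c (chromosome 2, 164769898 to 164778822) stood at 11.1 ± 4.76 CPM in TAK-243 and 37.2 ± 5.60 CPM in vehicle (SD, n = 4 each). S phase and replication genes had a median of 0.07 over 26 members, and this list was not called (camera adjusted p = 0.221, limma). It was called as higher without vehicle replicate 2 (median 0.12) and without TAK-243 replicate 4 (0.10), and its median was -0.034 without TAK-243 replicate 2. The uracil glycosylase Ung (0.72) was its only member past the threshold over the list alone, and it rose. No S phase member passed as higher in 8 of 21 alternatives, and 1 passed as lower without TAK-243 replicate 4. Per library, the G2/M list median relative to the vehicle mean was -1.13, -0.37, -0.39 and -1.03 in TAK-243 replicates 1 to 4 and 0.00, 0.14, 0.10 and -0.23 in vehicle replicates 1 to 4 (two-sided exact permutation p = 0.0286, the smallest possible).

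The G2/M list was called by camera (limma adjusted p = 1.3e-25) with the preset correlation of 0.01 but not with an estimated correlation (limma adjusted p = 0.582 with an estimated correlation). Without TAK-243 replicate 4, 12 members fell over the list alone, and without TAK-243 replicates 2 and 3 the median was -1.06.

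**Figure D3:**
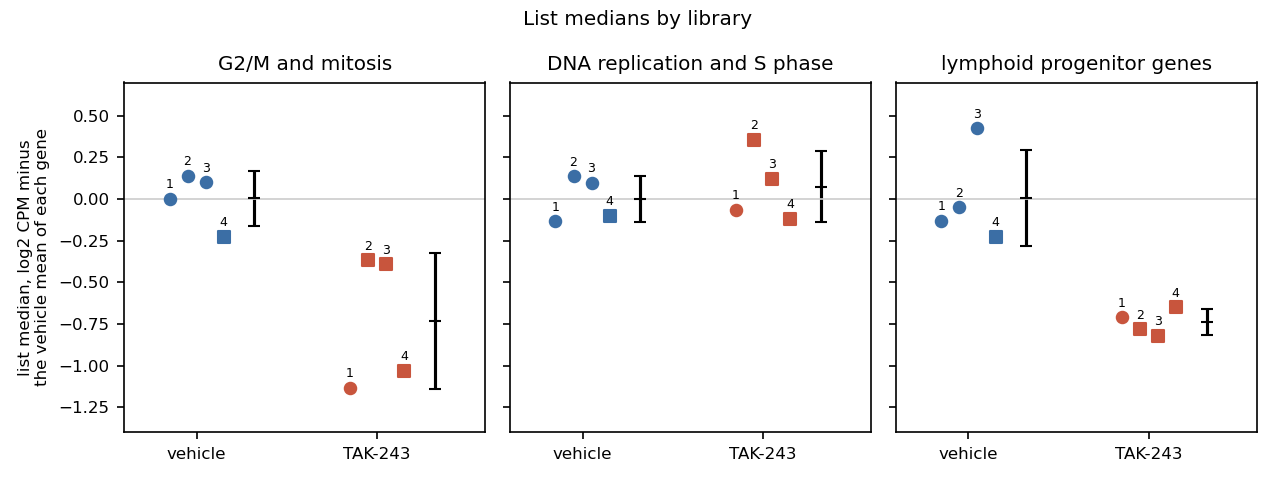
Median over list members of log2 CPM minus the vehicle mean of each gene, for 3 lists, in each library (numbers are replicates; circles are libraries with names under 1000, squares those over 1000), with mean ± SD of the 4 libraries in black. The lymphoid progenitor medians of TAK-243 libraries lie between -0.82 and -0.65, below the vehicle libraries, and the S phase medians overlap.

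Lymphoid progenitor genes were lower under TAK-243 by a similar amount. Of 20 measured members, 18 had a negative log2 fold change, the median was -0.72, and 10 fell when p was adjusted over the list alone, against 0 over all genes tested (edgeR). Dntt, which encodes the terminal transferase of antigen receptor rearrangement (chromosome 19, 41029275 to 41059525), stood at 202 ± 47.1 CPM in TAK-243 and 602 ± 205 CPM in vehicle (SD, n = 4 each; log2 fold change -1.57, SE 0.24; edgeR adjusted p = 0.0728 over all genes). The recombinase gene Rag1 (chromosome 2, 101638282 to 101649501) had 5.97 ± 3.12 and 24.6 ± 7.72 CPM (log2 fold change -2.06). Il7r, the receptor of a cytokine that lymphoid progenitors need (chromosome 15, 9505788 to 9530176), had 7.18 ± 2.43 and 22.3 ± 5.05 CPM (-1.63), and Il12a 33.4 ± 7.71 and 59.8 ± 4.54 CPM (-0.84). Over 22 alternatives, Dntt passed over all genes in 6, Il7r and Rag1 in 5 each and Il12a in 3. Per-library list medians were -0.71, -0.78, -0.82 and -0.65 in TAK-243 and -0.13, -0.05, 0.43 and -0.22 in vehicle (two-sided exact permutation p = 0.0286). The list was called by camera (limma adjusted p = 1.8e-12) but not with an estimated correlation (limma adjusted p = 0.468 with an estimated correlation). B cell and plasma cell genes, measured as a separate list, had a median of -0.40 and were not called.

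The library names fall into a range under 1000 (vehicle replicates 1 to 3 and TAK-243 replicate 1) and a range over 1000 (vehicle replicate 4 and TAK-243 replicates 2 to 4), and the labels do not say what the numbers mark. With the range as a covariate, edgeR again called 0 genes, Uba1 had a log2 fold change of -0.03, and 18 G2/M members and 8 lymphoid progenitor members fell over their lists alone. Within the range under 1000, the G2/M median was -1.13 in the TAK-243 library and 0.00 to 0.14 in vehicle; within the range over 1000, it was -1.03 to -0.37 in TAK-243 and -0.23 in the vehicle library. The lymphoid progenitor medians were -0.71 against -0.13 to 0.43, and -0.82 to -0.65 against -0.22, in the same order. With a single library on one side of each range, neither contrast has replicates in both groups. With the covariate, granulocyte and monocyte progenitor genes were called as higher (median 0.26), and nuclear-encoded oxidative phosphorylation genes were no longer called (-0.10). The oxidative phosphorylation list was called in 19 of 21 alternatives, with medians from -0.18 to -0.045.

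Other lists of blood cell states moved less. Haematopoietic stem cell genes had a median log2 fold change of -0.33 over 25 members, 22 of them negative and 0 past the threshold over the list alone (camera adjusted p = 0.00125, limma; adjusted p = 0.703 with an estimated correlation). Mllt3, a regulator of stem cell maintenance, stood at 53.6 ± 12.96 CPM in TAK-243 and 93.9 ± 22.3 CPM in vehicle (SD, n = 4 each), and the cell cycle inhibitor gene Cdkn1c at 1.69 ± 0.593 and 3.37 ± 0.781 CPM. Per library, the stem cell medians of the groups overlapped, at -0.28, -0.51, -0.57 and -0.04 in TAK-243 replicates 1 to 4 and 0.22, -0.0098, -0.47 and 0.27 in vehicle replicates 1 to 4 (two-sided exact permutation p = 0.114). Without TAK-243 replicates 2 and 3 the stem cell median was -0.18 and the list was not called. Stem cell genes fell over the list alone in 5 of 21 alternatives, at most 6 of them (without vehicle replicate 3). Granulocyte and monocyte progenitor genes (median 0.09 over 20 members; camera adjusted p = 0.0629), erythroid genes (0.07 over 18; 0.460) and megakaryocyte and platelet genes (-0.0073 over 14; 0.596) were not called, though the first list was called as higher in 8 of 21 alternatives, among them those without vehicle replicate 1 (0.13) or vehicle replicate 3 (0.20), and the erythroid list as lower in 2, without TAK-243 replicate 4 (-0.11) and with no filter on low counts. In the last list 1 member rose over the list alone, Itga2b (1.09), and 1 fell, Vwf, the von Willebrand factor gene (-1.96), which had 26.1 ± 10.99 CPM in TAK-243 and 101 ± 56.5 CPM in vehicle (SD, n = 4 each). No member of that list passed as lower over the list alone in 3 of 21 alternatives.

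Protein homeostasis genes showed small shifts. Cytosolic heat shock genes had a median log2 fold change of 0.19, with 17 of 19 members positive (camera adjusted p = 0.00497, limma; adjusted p = 0.703 with an estimated correlation). Hsph1, a chaperone of the HSP110 family, stood at 112 ± 28.8 CPM in TAK-243 and 67.4 ± 16.4 CPM in vehicle, and the HSP90 co-chaperone gene Fkbp4 at 218 ± 45.4 and 155 ± 18.3 CPM (SD, n = 4 each). The endoplasmic reticulum unfolded protein response list had a median of 0.06 over 21 members (camera adjusted p = 0.0261, limma; adjusted p = 0.703 with an estimated correlation), with Hyou1 at 0.52 and Edem1 at 0.37. No member of either list passed over the list alone in the edgeR fit of all 8 libraries with no setting altered. Over the list alone, 3 heat shock genes rose without TAK-243 replicate 4, 1 with no filter and 1 with the replicate block. The per-library medians of the groups overlapped for both lists (two-sided exact permutation p = 0.2 and 0.571). The heat shock call was lost in 4 of 21 alternatives, with no filter on low counts (median 0.14), without vehicle replicate 1 (0.13), without TAK-243 replicate 2 (0.11) and without TAK-243 replicates 2 and 3 (0.07), and the unfolded protein response call held in 14 of 21 alternatives. It was lost with no filter (median 0.03), with the replicate block (0.06) and without vehicle replicate 1 (0.0069), vehicle replicate 4 (0.05), TAK-243 replicate 1 (0.06), TAK-243 replicate 2 (0.11) or TAK-243 replicate 4 (0.07), while without vehicle replicate 2 and without TAK-243 replicate 3 the median was 0.12 and 0.15.

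Ubiquitin pathway lists were not called by camera. The median was -0.07 over 10 ubiquitin-like E1 enzymes (camera adjusted p = 0.748), where Sae1 had 0.25, and -0.12 over 30 E2 conjugating enzymes (0.231), where Ube2c was the only member that fell over the list alone. Of 4 ubiquitin genes (median 0.02; camera adjusted p = 0.460), Ubb fell over the list alone, from 2595 ± 154 CPM in vehicle to 1921 ± 211 CPM in TAK-243 (SD, n = 4 each; log2 fold change -0.43). No ubiquitin gene passed in 7 of 21 alternatives. Constitutive proteasome genes had a median of -0.07 over 33 members (camera adjusted p = 0.189; called as lower without vehicle replicate 4, -0.13, or TAK-243 replicate 2, -0.16), with Psmb6 at -0.50 and Psmb3 at -0.33, and 0 past the threshold over the list alone (1 fell without TAK-243 replicate 4). The ATF4 integrated stress response (median 0.07 over 23; camera adjusted p = 0.529), NRF2 oxidative stress (-0.16 over 20; 0.180), autophagy and lysosome (-0.05 over 26; 0.360), cholesterol biosynthesis (-0.019 over 24; 0.877) and Fanconi anaemia and homologous recombination lists (0.06 over 22; 0.596) were not called either. The NRF2 list was called as lower without vehicle replicate 4 (-0.19), and the Fanconi anaemia list as higher without TAK-243 replicate 4 (0.10) but as lower without TAK-243 replicates 2 and 3 (-0.11). Not called, too, were p53 targets (-0.11 over 23; 0.231), where the kinase gene Plk2 (-1.19) was the only member that fell over the list alone. With no filter on low counts, the E2 enzyme, ubiquitin, proteasome, NRF2, autophagy, cholesterol and p53 lists were called as lower, as were the B cell and plasma cell list and the dissociation and immediate early list.

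**Figure D4:**
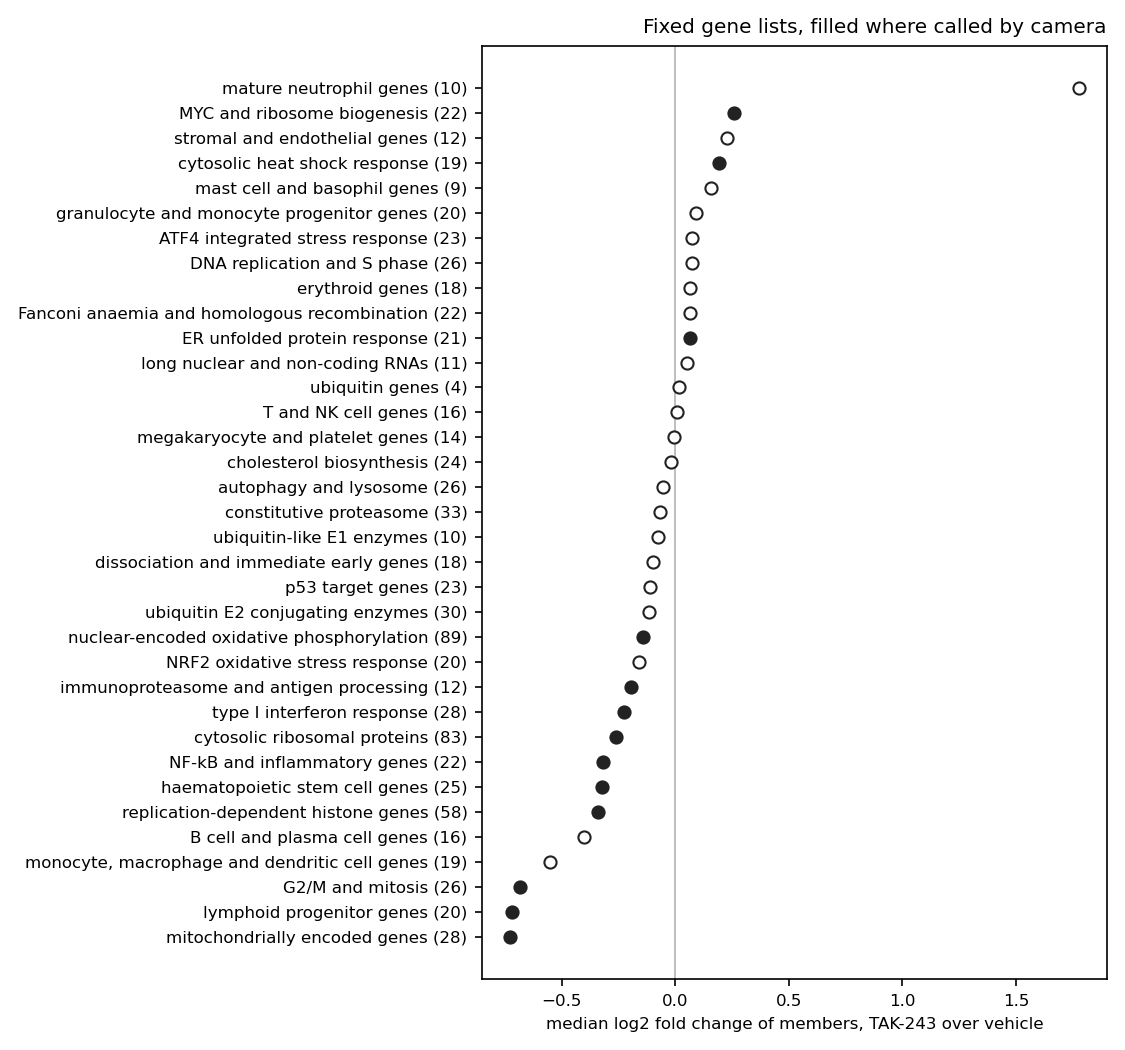
Median log2 fold change, TAK-243 over vehicle, of the measured members (number in brackets) of 35 gene lists, filled where camera gave an adjusted p under 0.05 with the preset correlation. The mature neutrophil median of 1.78 is not called, and G2/M, lymphoid progenitor and mitochondrially encoded genes have the lowest medians, from -0.73 to -0.68.

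Immune and inflammatory lists had negative medians over members, though the inflammatory median was not negative in every TAK-243 library. Type I interferon response genes had a median of -0.23 over 28 members (camera adjusted p = 0.000499, limma; adjusted p = 0.638 with an estimated correlation), with the RNA sensor gene Ifih1 at -0.37 and Zbp1, a sensor of Z-form nucleic acids, at -0.71. NF-kB and inflammatory genes had a median of -0.32 over 22 members (camera adjusted p = 0.00513, limma; adjusted p = 0.703 with an estimated correlation), and Tnf stood at 3.41 ± 0.662 CPM in TAK-243 and 7.65 ± 2.66 CPM in vehicle (SD, n = 4 each). Immunoproteasome and antigen processing genes had a median of -0.20 over 12 members (camera adjusted p = 0.00722, limma; adjusted p = 0.638 with an estimated correlation), with the peptide transporter gene Tap1 at -0.36 and B2m at -0.69. No member of these 3 lists passed over its list alone in the edgeR fit of all 8 libraries with no setting altered. Over their list alone, 4 inflammatory genes fell without TAK-243 replicate 4, 1 without vehicle replicate 1 and 1 with no filter. Likewise, 4 interferon genes fell without TAK-243 replicates 2 and 3. Per library, the interferon medians of the groups did not overlap (two-sided exact permutation p = 0.0286), while those of the antigen processing list (exact permutation p = 0.0857) and of the inflammatory list (exact permutation p = 0.257) did. The gap in the interferon list was narrow, with -0.079 the highest TAK-243 median and -0.068 the lowest vehicle median. The inflammatory medians were -0.58, -0.42, -0.10 and 0.04 in TAK-243 replicates 1 to 4 and -0.14, -0.12, 0.19 and -0.05 in vehicle replicates 1 to 4. Monocyte, macrophage and dendritic cell genes stood in the same order in the TAK-243 libraries (-1.36, -0.53, -0.15 and -0.07) but not in vehicle (0.59, -0.12, 0.78 and -0.64), and whether a change in those cells accounts for the inflammatory genes was not tested. Leaving out TAK-243 replicate 1 ended the inflammatory call (median -0.21) and the antigen processing call (-0.12), leaving out vehicle replicate 3 ended the inflammatory call (-0.13), and the number range with the GC and length offset ended the antigen processing call (-0.12). The interferon median was -0.12 without vehicle replicate 3 and -0.11 without TAK-243 replicate 1.

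Ribosome biogenesis genes and ribosomal protein genes had medians of opposite sign. MYC and ribosome biogenesis genes had a median of 0.26, with 20 of 22 members positive (camera adjusted p = 1.3e-06, limma; adjusted p = 0.638 with an estimated correlation). The rRNA methyltransferase gene Nop2 had 0.44 and Nop56, a nucleolar protein of box C/D particles, 0.48. Cytosolic ribosomal protein genes had a median of -0.26 over 83 members (camera adjusted p = 7.1e-09, limma; adjusted p = 0.638 with an estimated correlation), among them Rpl28 at -0.80 and Rpl19 at -0.66. Nuclear-encoded oxidative phosphorylation genes had -0.14 over 89 (camera adjusted p = 0.00332, limma; adjusted p = 0.703 with an estimated correlation), with Cox6c at -0.62, and mitochondrially encoded genes -0.73 over 28 (camera adjusted p = 3.9e-08, limma; adjusted p = 0.703 with an estimated correlation). No member of these 4 lists passed over its list alone in the edgeR fit of all 8 libraries with no setting altered. Ribosome biogenesis members rose over the list alone in 10 of 21 alternatives, among them 9 with limma-voom, 8 with upper-quartile scaling and 8 without TAK-243 replicate 3. Without TAK-243 replicate 4, 22 ribosomal protein genes and 4 oxidative phosphorylation genes fell over their lists alone and 1 ribosomal protein gene rose. With no filter, 3 ribosomal protein genes fell over the list alone. The per-library medians of the groups did not overlap for ribosomal protein genes (two-sided exact permutation p = 0.0286) and overlapped for ribosome biogenesis (0.143), oxidative phosphorylation (0.114) and mitochondrially encoded genes (0.0857). Without TAK-243 replicate 3, the medians of the ribosomal protein, oxidative phosphorylation and mitochondrially encoded lists were -0.16, -0.09 and -0.40, and without TAK-243 replicates 2 and 3 they were -0.14, -0.09 and -0.11, in the same order. The mitochondrial median was -1.10 without TAK-243 replicate 1. Replication-dependent histone genes had a median of -0.34 over 58 members, 2 of which, H2bc15 and Hist1h2bp, fell over the list alone (camera adjusted p = 1.6e-07, limma; adjusted p = 0.703 with an estimated correlation). Histone genes are near-identical copies, so their counts are uncertain, per library the groups overlapped (exact permutation p = 0.343), and without TAK-243 replicate 1 the list was not called (median -0.10). The median was -0.14 without TAK-243 replicate 2, -0.22 without vehicle replicate 1 and -0.78 with 11 members lower without TAK-243 replicate 4, and 0 members passed without vehicle replicates 1, 2 or 3 or TAK-243 replicates 1, 2 or 3.

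Markers of other cell types were measured because the sort could leave some of these cells behind. Mature neutrophil genes had a median of 1.78 over 10 members and were not called (camera adjusted p = 0.529). Their per-library medians were -0.73, 4.10, 0.72 and -2.11 in TAK-243 replicates 1 to 4 and -0.39, 0.65, 1.49 and -1.28 in vehicle replicates 1 to 4, and without TAK-243 replicate 2 the list median was -0.41, so that library carries the positive value. With limma-voom the median was -0.57. The list was called as higher without TAK-243 replicate 4 (2.31) and with the replicate block (0.42). S100a9 was at 48.6 CPM and Ltf at 48.1 CPM in TAK-243 replicate 2, while the other 3 TAK-243 libraries had at most 0.396 and 1.41 CPM and the vehicle libraries at most 5.51 and 2.57. Monocyte, macrophage and dendritic cell genes (median -0.55 over 19; camera adjusted p = 0.114), B cell and plasma cell genes (-0.40 over 16; 0.180), T and NK cell genes (0.0055 over 16; 0.748), mast cell and basophil genes (0.16 over 9; 0.529) and stromal and endothelial genes (0.23 over 12; 0.879) were not called. The first of these was called as lower without vehicle replicate 2 (-0.84), vehicle replicate 4 (-0.73) or TAK-243 replicate 3 (-0.89), and with no filter (-0.72), the replicate block (-0.45) or the GC and length offset (-0.53). Their most abundant members, Lyz2 (57.4 ± 19.2 and 73.1 ± 6.89 CPM in TAK-243 and vehicle), Ighm (566 ± 244 and 595 ± 139), Nkg7 (27.8 ± 5.74 and 23.2 ± 0.958), Cpa3 (24.9 ± 14.7 and 17.8 ± 3.85) and Runx2 (152 ± 35.4 and 196 ± 18.4), were not called by edgeR (SD, n = 4 each), and their groups overlapped. Ighd, an immunoglobulin heavy chain gene of mature B cells, fell over its list alone (-1.17). No member of it passed in 8 of 21 alternatives. Of the mast cell and basophil list, Cd200r3 rose (1.27) and Il1rl1 fell (-0.94) over the list alone. No member of it passed in 10 of 21 alternatives. Of the stromal and endothelial list, Pdgfrb (0.55), Sparc (1.62) and Col1a1 (2.53) rose and Stab2 (-1.29) and Emcn (-1.09) fell over the list alone, Col1a1 being named after its values were seen. Leaving out any 1 library except TAK-243 replicate 3 left at most 1 lower member of the stromal and endothelial list past the threshold. With the number range or the replicate block no member of this list or of the mast cell and basophil list passed.

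Signs of RNA quality other than the mitochondrial and histone lists were not called. Long nuclear and non-coding RNAs had a median of 0.05 over 11 members (camera adjusted p = 0.695), with the small nucleolar RNA host gene Gas5 at 489 ± 91.3 CPM in TAK-243 and 342 ± 34.9 CPM in vehicle. Dissociation and immediate early genes had a median of -0.10 over 18 members (camera adjusted p = 0.748; called as lower without TAK-243 replicate 4, -0.45), and Fos stood at 184 ± 102 CPM in TAK-243 and 91.5 ± 12.7 CPM in vehicle (SD, n = 4 each). In 8 lists, none of them called, the median, the mean and the direction of the camera test did not have 1 sign. The test pointed up with a negative median for E1 enzymes (mean -0.0071), cholesterol biosynthesis (mean -0.034) and megakaryocyte genes (mean -0.22), and down with a positive median for ubiquitin genes (mean -0.09), erythroid genes (mean 0.08) and stromal genes (mean 0.18). For long non-coding RNAs it pointed up with a mean of -0.14, and for dissociation genes down with a mean of 0.07.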

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

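Of the tests in this part, the fits without TAK-243 replicates 2 and 3, the comparison of the G2/M with the S phase list, the ranking of splits by list median, the background subtraction and the GC and length offset were chosen after the results were seen. A library was singled out where its gap to the nearest library of its group, over the group's range, exceeded Dixon's critical value. That happened for 11 results among 192 groups of 4 values; chance alone gives about 1 in 20 groups, or 9.6.

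In TAK-243 replicate 3, olfactory receptor genes took 539.4 CPM, against at most 118.4 CPM in the other TAK-243 libraries and 50.6 to 64.8 CPM in vehicle. Most of these genes are silent in blood cells, but Olfr56 was tested and called lower in TAK-243 by DESeq2 (log2 fold change -0.77). TAK-243 replicate 3 also had the fewest counts and the lowest correlation with the rest. Lower depth as the cause is argued against by thinning: with every library thinned to 13675642 counts, the lowest median correlation among the other 7 libraries was 0.956, above the 0.916 of TAK-243 replicate 3 by more than the SD of 5 thinnings (0.00047). After a background of reads spread over the genome in proportion to length was taken off, its median correlation was 0.890 and the lowest of the others 0.949. This cannot decide whether such reads are the whole cause. Only their expected number was subtracted, so their sampling noise stays in genes with low counts. What sets the library apart stays open, and no biological explanation was tested.

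In TAK-243 replicate 2, S100a9 (48.6 CPM; nearest of its group 0.396) and Ltf (48.1 CPM; nearest 1.41), both abundant in mature neutrophils, were far above the rest of the group and above the vehicle libraries, which had at most 5.51 and 2.57 CPM. In TAK-243 replicate 3, the small nuclear RNA gene Rn7sk was at 6396.1 CPM (nearest 2920.8), within the vehicle range of 4402.9 to 8064.1 CPM, so the other 3 TAK-243 libraries were the low ones; without this replicate edgeR called the gene lower (log2 fold change -1.25; adjusted p = 0.04996, with a range of 0.04996 to 0.707 over its alternatives). In TAK-243 replicate 4, Rpl19 was at 820.2 CPM (nearest 510.4), within the vehicle range of 792 to 951 CPM, while Serpinf1 at 23.7 CPM (nearest 18.0) and Gas6 at 3.92 CPM (nearest 2.30) stayed below every vehicle library. In TAK-243 replicate 1, haemoglobin genes took 0.00138% of counts (nearest 0.00921%; vehicle 0.00177% to 0.00763%) and Plk2 was at 7.34 CPM (nearest 11.7). In vehicle replicate 1, Stx3 was at 19.3 CPM (nearest 22.9). In vehicle replicate 3, Plk2 was at 31.4 CPM (nearest 22.4).

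For the lower G2/M genes under TAK-243, TAK-243 replicates 2 and 3, which stand apart, had list medians of -0.37 and -0.39. TAK-243 replicates 1 and 4 had -1.13 and -1.03, which argues against the libraries that stand apart as the cause. Without TAK-243 replicates 2 and 3 all 26 members fell over the list alone. These medians made that outcome likely beforehand, so it adds no separate support. A GC or transcript length bias is argued against, since with the offset the list median was -0.61, against -0.68 without it. A smaller share of cycling cells as the whole cause would lower S phase genes alike. The S phase list median per library was 0.075 ± 0.215 in TAK-243 and 0.00089 ± 0.136 in vehicle (SD, n = 4 each), which argues against it. The G2/M minus S phase difference per library was -0.81 ± 0.239 in TAK-243 and 0.00 ± 0.107 in vehicle (SD, n = 4 each; two-sided exact permutation p = 0.0286, the smallest possible). The results of both lists had been seen before, so that p adds no separate support. By the number of members past the threshold over the list alone, chance could not be excluded: 2 of 35 splits gave as many, with 20 in the real split and 21 in the split that exchanges vehicle replicate 4 and TAK-243 replicate 2, although by the size of the list median the real split was the highest (0.68, next 0.67). A change in G2/M under the inhibitor therefore stays an open hypothesis.

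For the lower lymphoid progenitor genes, TAK-243 replicates 1 and 4 had list medians of -0.71 and -0.65, below the vehicle libraries (-0.22 to 0.43). That argues against the libraries that stand apart as the cause. Without TAK-243 replicates 2 and 3, 9 members fell over the list alone. The medians made that outcome likely beforehand, so it adds no separate support. With the GC and length offset the list median was -0.67, against -0.72 without it, which argues against a GC or transcript length bias. By the number of members, 1 of 35 splits, the real one, gave 10 members, and the highest other split gave 1. Chance is not excluded by this, since the list was singled out by its result in the real split. The splits also exchange libraries across the 2 number ranges, which partly follow the treatment. By the size of the list median chance could not be excluded either, since 2 of 35 splits reached the real 0.722. The other was the exchange of vehicle replicate 4 and TAK-243 replicate 4 (0.727). Fewer mature B cells in the TAK-243 libraries cannot be told apart from a change in progenitors: 10 measured mature B cell genes had a median of -0.41, only 0.31 above the progenitor list, with a bootstrap SE of 0.37. Those genes are low in these cells, with a median of 2.97 CPM in vehicle against 39.8 CPM for the progenitor list, and a sort for lineage-negative cells would remove most B cells.

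For the calls over all genes, the splits gave a mixed picture. The real split had 2430 genes at an unadjusted p under 0.05 by edgeR, more than any other (highest 2296), so 1 of 35 splits reached it. Chance is not excluded by that count, since the splits exchange libraries across the 2 number ranges, which partly follow the treatment. At an adjusted p under 0.05 by edgeR the comparison decides nothing about chance, since the real split called 0 genes and all 35 splits reach 0 by construction (highest other 51). The split by the number range of the library names called 38, and with that range as a covariate the treatment called 0. DESeq2 called 462 in the real split and 560 in another, and limma-voom 109 and 370, so 2 of 35 splits reached each count and chance could not be excluded. Of the gene lists, 14 of 35 splits called as many as the real 13, with up to 17, so chance could not be excluded for that number. The split with 560, 370 and 51 genes exchanges vehicle replicate 4 and TAK-243 replicate 4 and points to a structure of the samples beyond the treatment. Its genes called by edgeR had a median GC content of 57.4%, against 48.7% over tested genes, and with the GC and length offset it called 16.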

How the results depend on the processing

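The fit without TAK-243 replicates 2 and 3, the background subtraction, the GC and length offset and its combination with the number range were chosen after the data were seen; the other alternatives were planned. The edgeR count of 0 genes held with upper-quartile scaling, total counts, the number range with and without the GC and length offset, the test against 1.5-fold and the background subtraction. It became 5 (1 higher, 4 lower) with RLE factors, with the stricter filter and with abundant RNA classes removed, 80 (12 higher, 68 lower) with no filter, 462 (196 and 266) with DESeq2, 109 (26 and 83) with limma-voom, 35 (5 and 30) at an adjusted p under 0.10, 140 (18 and 122) without TAK-243 replicates 2 and 3 and 16 (4 and 12) with the GC and length offset. Leaving out single libraries gave 0 to 49 genes in all, 0 to 11 higher and 0 to 38 lower, with 49 without TAK-243 replicate 3, 2 without TAK-243 replicate 2 and 4 without TAK-243 replicate 4. Fewer libraries or genes enter some of these fits; otherwise the cause was not tested. With no filter the median log2 fold change of all genes was 0.17, and in the other fits it stayed within 0.06 of 0.

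With the replicate number as a block, 2 genes were called, both lower (0 higher). The numbers do not pair the samples: same-numbered libraries had correlations of -0.05 to -0.00062 between their deviations, 0 of 4 pairs over 0.1, and 0 of 8 libraries correlated best with their own number.

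The number of called lists, 13 in the report, was 22 with no filter, 0 with an estimated correlation and 0 with fry, and 9 to 17 without single libraries. The G2/M members past the threshold over the list alone numbered 12 to 24 and the lymphoid progenitor members 8 to 12 when single libraries were left out. The Uba1 log2 fold change lay between -0.24 and 0.01 over 22 alternatives and passed in 0 of them; it was 0.0052 with the number range and the GC and length offset, a reversed sign with no call. The medians of the 13 called lists had 1 sign in every alternative that gave one. The S phase list, not called, was 0.036 with no filter, where its test pointed down, -0.034 to 0.18 without single libraries (lowest without TAK-243 replicate 2) and -0.082 without TAK-243 replicates 2 and 3. Among named genes that were never called, Ltf was -1.95 and S100a9 -0.76 with limma-voom, -1.48 and -3.01 without TAK-243 replicate 2 (highest without vehicle replicate 3, 3.61 and 3.65), and -3.26 and -2.94 without TAK-243 replicates 2 and 3. Ighm was 0.044 with limma-voom, 0.10 with the number range, 0.15 with that and the offset, -0.28 to 0.19 without single libraries (0.08 without vehicle replicate 2, 0.19 without TAK-243 replicate 3) and 0.27 without TAK-243 replicates 2 and 3. Rps27a was -0.031 to 0.12 without single libraries (-0.0024 without vehicle replicate 2) and -0.016 without TAK-243 replicates 2 and 3, where Sae1 was -0.0020. The cause of these changes of sign in near-zero or single-library values was not tested. Depth limits TAK-243 replicate 3 most, at 13675642 counts.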

Other observations

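All tests and genes in this part were chosen after values were seen, and none of the TAK-243 differences named here passed an adjusted p of 0.05 in the edgeR fit of all 8 libraries with no setting altered. Without TAK-243 replicate 3, edgeR called 7 of them as lower, Igf2r (adjusted p = 0.00656), Sgsm1 (0.0186), Iigp1 (0.0191), Arpp21 (0.0292), Gbp10 (0.0292), Gbp4 (0.0399) and Airn (0.0444), and DESeq2 and limma-voom called the same 7 over all libraries. DESeq2 also called Cd74 and H2-Aa as lower. Guanylate-binding protein genes, interferon-inducible GTPases of cell-autonomous immunity, were lower in TAK-243 on chromosome 5: 6 of 6 had a negative log2 fold change, with a median of -1.69, and 5 had groups that did not overlap. Gbp4 (chromosome 5, 105115767 to 105139586) stood at 3.34 ± 1.12 CPM in TAK-243 and 11.6 ± 2.81 CPM in vehicle, and Gbp10 at 1.20 ± 0.382 and 5.23 ± 1.09 CPM (SD, n = 4 each). The 4 members on chromosome 3 had a median of -0.29, and 7 other interferon-inducible GTPase genes -0.53, among them Iigp1 at 11.5 ± 4.58 and 30.2 ± 1.10 CPM. The gene models of Gbp4, Gbp8 and Gbp9 overlap on the same strand, so the 6 genes on chromosome 5 may not be separate observations. Reads may also be shared between members with similar sequence, which was not tested here. The interferon list of the report had a median of -0.12 without vehicle replicate 3.

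Igf2r, an imprinted receptor gene (chromosome 17, 12682406 to 12769664), stood at 19.2 ± 11.7 CPM in TAK-243 and 68.7 ± 4.34 CPM in vehicle, and its antisense transcript Airn at 1.35 ± 0.895 and 6.34 ± 1.81 CPM (SD, n = 4 each). Airn overlaps Igf2r on the opposite strand, and the use of strand in counting is unknown. Reads counted for Airn may come from Igf2r, so the lower Airn value may not be a separate result. The neighbouring Slc22a3 had a log2 fold change of 0.28. Sgsm1 (-1.96) and Arpp21 (-1.51) were lower in all 4 TAK-243 libraries than in any vehicle library. Of the MHC class II genes, Cd74 had -0.95, H2-Aa -0.94 and H2-Ab1 -0.58. The inducible heat shock genes Hspa1a and Hspa1b were at 93.7 and 121 CPM in TAK-243 replicate 3, at 13.6 and 17.2 CPM in TAK-243 replicate 2 and at 15.5 and 18.1 CPM in vehicle replicate 3.

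Genes with small p that lie together could mark a chromosome segment that differs between the mice of the 2 groups. Among the 200 genes with the smallest p, 28 pairs lay within 500 kb, against a median of 15 and a 95th percentile of 22 in 1000 random sets (one-sided permutation p = 0.00999). A looser form of this test, with overlapping genes kept, was run first. As 9 of 35 splits of the libraries gave as many pairs, with up to 124, a segment cannot be told apart from the clustering that other splits show.

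Libraries with names over 1000 differed from those under 1000 in 38 genes by edgeR, 28 higher and 10 lower (45 by limma-voom, 84 by DESeq2). Of these, 13 lie on chromosome 14 between 63 and 71 Mb, where 98 genes were tested. Some of the 13 may be copies that share reads. Gm20236 and Gm37094 both had a mean of 6.185 CPM under 1000, and 28.0 and 28.2 CPM over 1000. The 13 may therefore not be separate observations. Mtmr9 stood at 39.1 CPM under 1000 and 213 CPM over 1000, the ribosomal protein gene copy Rps3a3 at 10.7 and 246 CPM, Mid1 at 510 and 50.9 CPM and Naip5 at 62.6 and 4.58 CPM. A candidate explanation is that the ranges hold 2 stocks of mice that differ in genes present or expressed. In this split, 4 genes were under 0.2 CPM in all 4 libraries of 1 side and over 1 CPM in all 4 of the other, against at most 3 in any other split and 0 in the TAK-243 split. Among the 4, Gm38378 and Gm37513 both had a mean of 0.0123 CPM under 1000, and 7.25 and 7.27 CPM over 1000, so they may share reads. The margin is 1 gene and may not hold if these 2 count as 1. Age or a sequencing batch stay open, since the labels do not say what the numbers mark.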
